A study of Mus musculus with 140 samples.

How the data were processed

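RNA was sequenced from femurs and otic capsules of oim mice, a model of osteogenesis imperfecta in which a small deletion in Col1a2 keeps the pro-alpha2 chain out of type I collagen. Per the labels, the mice were of the strain B6C3Fe a/a-Col1a2oim/J, came from crosses of heterozygous parents, and were wild type (WT), heterozygous (HET) or homozygous for oim (OIM). They were sampled at 12 or 25 weeks of age, and both sexes were used. The labels call the ear tissue "Ossicle" in titles and "otic capsule" in the protocol, and it is called otic capsule here. The femurs had been flushed of marrow, per the labels' protocols, and the polyA libraries were not stranded and were read as pairs of 50 bases, so reads of a gene and of its antisense partner cannot be told apart. The 140 libraries fall into 12 groups of 9 to 16 libraries, from 71 mice, of which 69 gave both tissues. Per the labels each library of a tissue comes from another mouse, so the spread between libraries of a group is read as a spread between animals, though the labels of 4 mice are in doubt. The 67 female libraries were all in batch l4, and the male libraries were in batches l1 to l3 but for 1 femur and 2 otic capsule libraries.

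The authors deposited read counts per gene, and per the submitters' processing notes they used fastp 0.19.10, STAR 2.7.3a, SAMtools 1.9, featureCounts 2.0.1, R 4.5.2 and edgeR 4.8 with the mouse build mm10. The settings of these steps are not given in the sources used here. How reads that fit several genes were counted is also not given there, so genes with close copies, such as the Bglap, haemoglobin, Ly6 and immunoglobulin genes, carry that uncertainty. There were 2 deposited tables of all counts, with 30167 and 30153 genes, and 0 values differed between them over the 30153 shared genes. The first table was used, and the other changed no result. The authors also deposited tables of their own comparisons, with a log2 fold change, a p-value and an adjusted p-value per gene, which are cited as the authors' deposited table. A further 4 deposited tables were not used here: 2 hold filtered rows of the same counts, and 2 hold log2 CPM on a scale that the counts did not return.

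The total count per library ran from 3548423 to 11564581, with a mean of 7609480. Levels are given in CPM, counts scaled to the same total in every library. A gene at 10 CPM has 35.5 counts in the shallowest library and 115.6 in the deepest one. Limits set by a count of 0 use 3 counts over the group. They and all intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

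Counts were tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F test with robust dispersions, TMM scaling and filterByExpr on the group (minimum count 10), which kept 16490 genes in femur, 18346 in otic capsule and 19302 over both tissues. Each tissue was fitted over its 70 libraries with a factor for the 6 groups of genotype and age plus sex and batch. Genotypes are therefore compared with sex and batch as additive terms. They were unbalanced over the male batches in femur: at each age the 6 OIM males were all in l3. Of the 12-week WT males 3 were in l2 and 1 in l3. Among 12-week male femurs the comparison of OIM and WT within a batch thus rests on 1 WT library. The sex comparison has no batch term, because sex and batch coincide but for 3 libraries, and its value is one of sex or batch. The tissue comparison and its interaction with genotype were fitted over all 140 libraries, with sex per tissue and batch. A gene passed where the Benjamini-Hochberg adjusted p of its comparison was under 0.05, two-sided. Standard errors (SE) are the absolute log2 fold change divided by the root of F. Where the text gives an adjusted p without naming another tool, it comes from this edgeR test. There were 20 such comparisons.

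The 30 gene lists, the 20 comparisons, their tests and the rule for the named genes were fixed before the data were examined. The rule named, for each comparison, the 5 genes with the largest positive and the 5 with the largest negative log2 fold change among those that passed and had a mean log2 CPM of at least 1, leaving out unnamed gene models. It also named the 3 members with the smallest adjusted p of each gene list, in the comparisons of OIM and WT for every list and in the others for lists called by camera, and Col1a1 and Col1a2. Clone names of another form, such as CT010467.1, were not covered by the rule for unnamed models and stay in. The list genes were matched by symbol; 1 was found under an older symbol (Ankh as Ank) and 2 had no row in the count table. Lists were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison. The camera test with the correlation estimated from the data and fry were run beside it. "Adjusted over the list alone" means that the p-values of the list's members were adjusted among themselves. After the data were examined, 7 further lists were added, for pituitary, salivary gland, serous gland secretion, hind limb homeobox genes, head genes, clock and glucocorticoid genes, and brown adipocytes.

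Each tool was tested on simulated counts made from the real means and library sizes, with 200 genes changed. For OIM against WT in femur at 12 weeks, edgeR called 34.33% of the genes changed 1.5-fold, 74.63% of those changed 2-fold and 92.42% of those changed 4-fold, and 8 of its 142 calls were false. For otic capsule at 12 weeks the shares were 53.73%, 73.13% and 95.45%, with 8 false calls of 156. For the interaction of genotype with tissue they were 32.84%, 61.19% and 90.91%, with 10 false calls of 133. These simulations drew each gene independently, so they lack the variation between libraries that genes share. The shares called and false therefore need not hold for the real counts.

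Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom with sample quality weights, size factors of the DESeq2 kind in edgeR, no low-count filter, designs without batch or without batch and sex, each sex alone, scores for blood cells and muscle as covariates, and the replicate number of the titles or the mouse as a block. Those added afterwards left out libraries of doubted label or content, left out 1 otic capsule library, or used muscle or gland scores as covariates. The mouse pairs the tissues, per the labels, and the median correlation between the femur and the otic capsule of a mouse was 0.177.

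No pair of libraries agreed within counting noise: the lowest chi-square per degree of freedom between libraries of a tissue was 5.09. Xist lay above the 4 Y-linked genes measured in all 67 female libraries and below them in all 73 male ones. The 7 libraries whose mouse or tissue label other libraries contradict, and the 6 with RNA of another tissue or mostly muscle, stayed in under their labels; they are named where they matter, and were chosen after the data were examined. A named gene that passed neither as reported nor under an alternative, and whose fold change then had the other sign, was counted as holding its result.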

Results

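RNA-seq counts were compared in 70 femur and 70 otic capsule libraries of WT, HET and OIM mice aged 12 or 25 weeks. At 12 weeks each tissue had 10 WT, 11 HET and 12 OIM libraries. At 25 weeks there were 15 WT, 10 HET and 12 OIM femur libraries, and 16 WT, 9 HET and 12 OIM otic capsule libraries. The median total count per library was 8070643.5 in femur and 7236455.5 in otic capsule. The question was which transcripts differ with the loss of the pro-alpha2 chain of type I collagen in a weight-bearing long bone and in the bone that encloses the inner ear. In femur, the first principal component held 35% of the variance. Its absolute correlation was 0.825 with the skeletal muscle score and 0.853 with the neutrophil score. Genotype accounted for 4.87% of it. In otic capsule, the second component held 18.5% of the variance, and its absolute correlation with the airway epithelium score was 0.824. Of its own variance 29.9% lay between genotypes.

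The femur of OIM mice at 12 weeks had higher levels of transcripts for making and mineralizing bone matrix. Panx3, a channel protein of maturing osteoblasts, rose by 3.15 on the log2 scale (SE 0.62, adjusted p 0.00322), and lay above the WT median in 12 of 12 OIM libraries. Alpl, which frees phosphate for mineral, rose by 1.29, the osteoblast glycoprotein gene Pdpn by 1.01, the homeobox gene Irx5 by 1.81 and the carbonic anhydrase gene Car12 by 2.37. Col1a1, which encodes the partner of the missing chain, rose by 1.85 (SE 0.50, adjusted p 0.0246, 12 of 12 libraries), from a mean of 2660 CPM (SD 1330) in WT to 8890 CPM (SD 4430) in OIM. Col1a2 itself, whose transcript carries the oim deletion, had a log2 fold change of 1.40 (SE 0.47) that missed the threshold (adjusted p 0.0853), although 12 of 12 OIM libraries lay above the WT median. Its means were 2970 CPM (SD 1550) in WT, 3640 (SD 1860) in HET and 7260 (SD 3520) in OIM. The machinery that modifies and folds procollagen rose too. P3h1, the prolyl 3-hydroxylase mutated in a recessive form of the disease, rose by 1.18 (SE 0.22, adjusted p 0.0027). Kdelr2, which returns chaperones to the endoplasmic reticulum, rose by 0.92, P4hb by 0.49 and Serpinf1 by 1.51, all of them in 12 of 12 libraries.

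**Figure D1:**
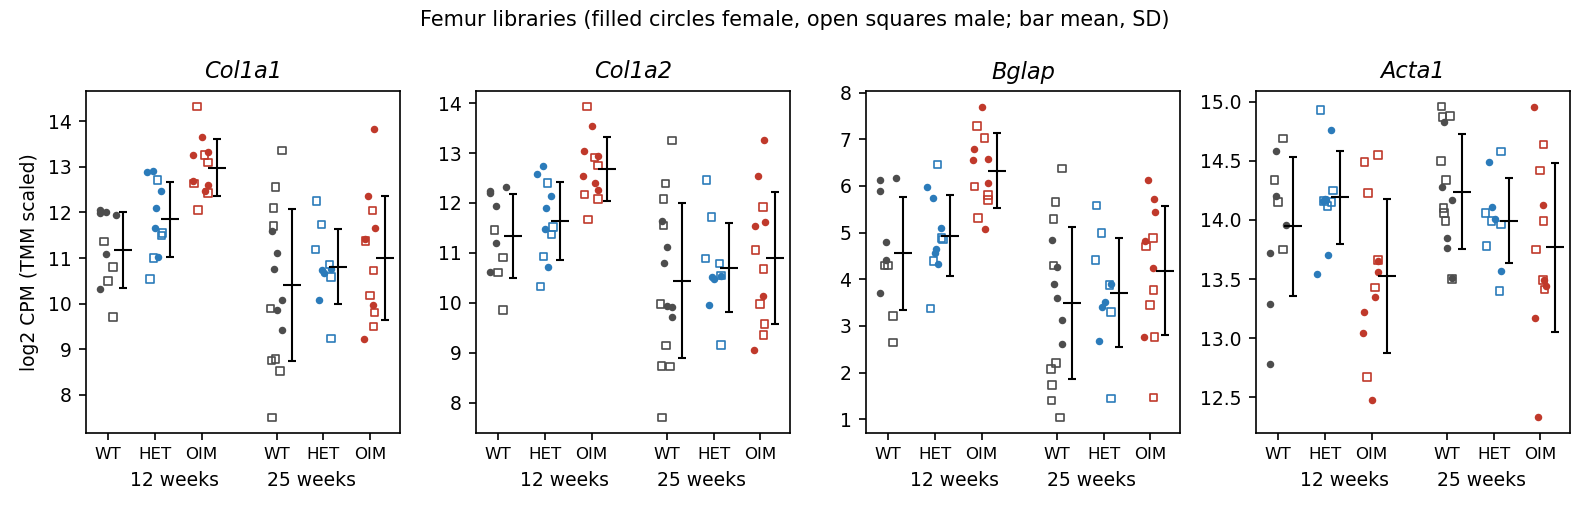
Levels of Col1a1, Col1a2, Bglap and Acta1 in each femur library, as log2 CPM, by genotype and age; each point is 1 mouse and the bars give the group mean and SD. At 12 weeks the OIM points of Col1a1 and Col1a2 lie above the WT median in 12 of 12 libraries, and at 25 weeks they overlap the WT points.

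Signals and enzymes that act around bone cells also rose in OIM femur at 12 weeks. Among Wnt pathway genes, Dkk1, a secreted inhibitor made by osteoblasts and osteocytes, rose by 2.43 (SE 0.56, adjusted p 0.00879), the feedback inhibitor Notum by 1.67 and the transcription factor gene Tcf7 by 1.59. Cthrc1, which is secreted by matrix-forming cells, rose by 2.34 (SE 0.41, adjusted p 0.00138, 12 of 12 libraries). The matrix genes Bgn, Mmp14, Mmp2, Col6a2 and Col6a1 rose by 1.35, 1.41, 1.22, 1.29 and 1.26. Pdgfra rose by 0.98, Cdkn1a by 0.93, the prostaglandin synthase gene Ptgs2 by 1.9 and Rpl39l by 1.44. The osteoclast genes Ctsk and Acp5 rose by 1.44 (SE 0.41, adjusted p 0.0334) and 1.42 (SE 0.42, adjusted p 0.0446), each in 11 of 12 libraries. Of the slow-muscle myosin locus, Mhrt fell by 1.61 and Myh7 by 1.48 (not called), and since Mhrt overlaps Myh7 on the other strand, unstranded reads do not show which RNA fell. Ly6a2 fell by 3.15. The pituitary hormone genes Prl and Gh fell by 7.27 (SE 1.36, adjusted p 0.0027, 10 of 12 libraries) and 4.8 (SE 1.08, adjusted p 0.0069, 8 of 12), and Col7a1 by 1.72 (7 of 12).

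In all, edgeR called 544 of 16490 femur genes in OIM against WT at 12 weeks, 483 higher and 61 lower. With the muscle score in the model 27 were called, with blood cell and muscle scores 2, and in females or males alone 0. Of the 39 bone matrix, osteoblast and osteocyte genes 19 were called, and 1 with the muscle score. The authors' deposited table has 915 genes for this comparison with the sexes averaged, and 1086 without sex in the model. Of 22 bone matrix and osteoblast genes 14 were called, all higher, or 21 adjusted over the list alone, with a median log2 fold change of 1.41. The counts were 16 of 26 (21 higher and 1 lower adjusted over the list alone) for collagen processing, 15 of 20 (17 higher and 1 lower) for osteogenesis imperfecta disease genes. They were 9 of 22 (14) for matrix proteases and small proteoglycans, 6 of 15 (7) for tendon and fibroblast, 5 of 24 (15) for the Wnt pathway. For bone cells they were 5 of 17 (12) for osteocytes and 2 of 16 (6) for osteoclasts, and 1 of 18 (4) for the TGF-beta pathway. Camera placed the bone matrix list above the other genes with an adjusted p of 4.92e-21. With the correlation estimated from the data its adjusted p was 0.0905, and no list passed that way. By fry, which tests the members alone, the bone matrix list had an adjusted p of 0.00194. Chondrocyte and macrophage genes had medians of 1.29 and 0.54 (0 called each, 3 and 6 adjusted over the list alone), adipocyte genes 0.95 and unfolded protein response genes 0.19 (0 and 0 for both). Lower by camera were oxidative phosphorylation (median log2 fold change -0.36, adjusted p 1.74e-14, with an adjusted p of 0.399 under the estimated correlation). So were mitochondrially encoded genes (-0.59; 8 of 10 lower adjusted over the list alone) and skeletal muscle (-0.45). Leaving out single libraries ended 13 of the 31 named calls. Prl, Gh and Ly6a2 lost theirs without the WT library 5, where Prl went to -2.05 and Gh to -1.81, and Col7a1 without the WT library 3, at -0.63. Without the OIM library 6 the calls of Col1a1 (1.69, adjusted p 0.0569), Ctsk (1.22), Acp5 (1.24), Col6a1 (1.05), Col6a2 (1.09), Pdgfra (0.84), Irx5 (1.71), Ptgs2 (1.66) and Mhrt (-1.50) ended at nearly the same fold changes. The call of Mhrt ended without any of 23 libraries, that of Acp5 without any of 14, Ctsk 6, Col1a1 3, Irx5 2 and Pdgfra 2.

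At 25 weeks edgeR called no gene between OIM and WT femur. Of the osteocyte genes, Sost, a Wnt inhibitor, had a log2 fold change of 3.17 (SE 0.76, adjusted p 0.232, above the WT median in 8 of 12 OIM libraries) and Mepe of 2.42 (SE 0.65, 9 of 12). Col1a1 had a log2 fold change of 0.28 (SE 0.44) and Col1a2 of 0.13 (SE 0.43). The 483 genes higher at 12 weeks had a median of 0.14, and 409 of them kept the sign. Interferon response genes had the smallest camera p at this age (median 0.45, adjusted p 3.68e-08, 4 of 15 higher adjusted over the list alone), at an adjusted p of 0.505 with the correlation estimated. Further lists placed by camera, all with an estimated adjusted p of 0.505 or more, were inflammatory cytokines (median 0.76, 3 of 7 higher adjusted over the list alone), osteoclast (0.50), neutrophil (0.52), osteocyte (0.43, 6 higher and 1 lower adjusted over the list alone), bone matrix (0.32), T and NK cell (0.24) and skeletal muscle (-0.30). The count by edgeR was 0, with 1165 genes at an unadjusted p under 0.05, 5 genes by DESeq2 and 495 by voom. The authors' deposited table has 0 genes with the sexes averaged and 5 without sex in the model.

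The difference between the ages was itself tested for OIM against WT femur. No gene passed by edgeR (1503 at an unadjusted p under 0.05, 0 by DESeq2, 13 by voom), and the authors' deposited table has 2 without sex in the model. Among lists, collagen processing had a median interaction of -0.82 (16 of 26 lower at 25 weeks than at 12 adjusted over the list alone, camera adjusted p 9.6e-18), with an adjusted p of 0.159 once the correlation was estimated. The bone matrix list had a median of -1.10 (5 of 22 adjusted over the list alone), disease genes -1.04 (11 of 20), Wnt -0.79 (9 of 24) and mitochondrially encoded genes 0.75 (9 of 10 higher). The loss of the bone call at 25 weeks is therefore not shown as an age difference for single genes.

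Heterozygous femurs differed little from WT. At 12 weeks edgeR called 4 genes, all lower: Prl by 7.06 (SE 1.14, adjusted p 0.000701, 10 of 11 HET libraries below the WT median) and Gh by 5.84 (SE 0.97, adjusted p 0.000838, 10 of 11). The others were the death ligand gene Tnfsf10 by 1.60 (SE 0.32, adjusted p 0.0236, 11 of 11), and the imprinted antisense RNA Kcnq1ot1 by 0.65 (SE 0.12, adjusted p 0.0053, 11 of 11). Without the WT library 5, Prl went to -2.28 (adjusted p 0.948) and Gh to -2.85 (adjusted p 0.842). Tnfsf10 lost its call without any of 9 libraries and Kcnq1ot1 without the HET library 7 (-0.61, adjusted p 0.0524). Bone matrix genes had a median of 0.42 (camera adjusted p 1.69e-05), collagen processing 0.22, disease genes 0.29, osteoclast genes 0.37 and B cell genes -0.47, each with an adjusted p of 0.782 when the correlation was estimated and 0 members called. At 25 weeks 0 genes passed by edgeR (669 at an unadjusted p under 0.05, 0 by DESeq2, 4 by voom). Neutrophil genes had a median of 0.64 (camera adjusted p 9.46e-07, or an adjusted p of 0.947 with the estimated correlation).

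OIM and HET femurs, compared over both ages, differed in single genes, some of them of matrix, muscle and fat, and no gene list passed by fry or with the estimated correlation. Cthrc1 rose by 1.42 (SE 0.30, adjusted p 0.0127, above the HET median of its age in 20 of 24 OIM libraries), Cgref1 by 1.10 (22 of 24) and Cemip, a hyaluronan-degrading protein, by 1.24. Kazald1, which is made by osteoblasts, rose by 1.09, Galnt5 by 1, Notum by 1.22, the lysyl oxidase gene Loxl4 by 0.97 and P3h1 by 0.62. Timp4 fell by 0.96 (SE 0.18, adjusted p 0.00796, 21 of 24) and Rbp7, a retinol carrier of fat and vessels, by 1.21. Snai3, expressed in skeletal muscle, fell by 0.98, Cntfr by 0.85 and Zbtb16, which glucocorticoids induce, by 0.82. The count was 107 genes, 71 higher and 36 lower, against 610 without sex in the model in the authors' deposited table. In males alone 0 were called and by voom 2145, and 11 of 14 alternatives moved the count by more than 1.5 times. Bone matrix genes had a median of 0.80 (1 of 22 called, 18 adjusted over the list alone, camera adjusted p 3.05e-11, or an adjusted p of 0.557 with the estimated correlation). Collagen processing had 2 of 26 called (14 adjusted over the list alone) and skeletal muscle a median of -0.28 (3 of 17 lower adjusted over the list alone). Of the 13 named calls 5 ended without some library (Cemip, Loxl4, Notum, P3h1 and Zbtb16), and the count ran from 48 to 611 over the 38 libraries that moved it most.

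The otic capsule of OIM mice at 12 weeks had 554 of 585 called genes lower than WT, among them genes of epithelia, glands and the secretory pathway. Tekt1, a protein of cilia, fell by 1.10 (SE 0.22, adjusted p 0.0131, below the WT median in 12 of 12 OIM libraries), Dynlrb2, of the ciliary dynein, by 1.22 (12 of 12) and the epithelial keratin gene Krt8 by 1.38 (11 of 12). The chaperone gene Hyou1 fell by 0.49 (SE 0.10, adjusted p 0.0131), Pdia4 by 0.54, Sdf2l1 by 0.79 and the coat protein gene Sec24d, which loads procollagen for export, by 0.57, each in 12 of 12 libraries. The salivary genes Smr3a, Bpifa2 and Car6 fell by 6.40 (SE 1.46, adjusted p 0.0172, 8 of 12 libraries), 5.65 (SE 1.47, 10 of 12) and 5.21 (SE 1.19, 11 of 12). The pituitary hormone gene Fshb fell by 4.82 (SE 1.16, adjusted p 0.0199, 6 of 12) and Platr9 by 4.51 (7 of 12). The neutrophil genes Ly6g and Retnlg rose by 2.38 (SE 0.57, adjusted p 0.0199, 11 of 12) and 1.83 (11 of 12), and Prtn3 by 2.05 (10 of 12). The platelet gene Ppbp rose by 2.13 (8 of 12) and the B cell factor gene Pax5 by 1.41 (9 of 12). Type I collagen was not called: Col1a1 had a log2 fold change of 0.54 (SE 0.36) and Col1a2 of 0.23 (SE 0.33). The mean Col1a2 level was 1260 CPM (SD 768) in WT, 763 (SD 239) in HET and 1440 (SD 1730) in OIM, or 951 (SD 311) in OIM without the library 1, which holds femur transcripts and had 6840.

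In all, 585 of 18346 otic capsule genes were called, 31 higher and 554 lower, and 382 of them changed by more than 1 on the log2 scale. With the gland scores in the model 0 were called, in females alone 372, in males alone 1 and without the doubted libraries 284. The authors' deposited table has 811 genes with the sexes averaged and 668 without sex in the model. Of 23 unfolded protein response genes 10 were called lower, or 13 adjusted over the list alone (median -0.36, camera adjusted p 1.18e-09, and an adjusted p of 0.358 with the estimated correlation). Middle ear airway epithelium had 5 of 13 called lower (11 adjusted over the list alone, median -1.38, camera adjusted p 8.14e-17, and an adjusted p of 0.142 with the estimated correlation). Higher by camera were erythroid genes (median 1.69, 8 of 14 adjusted over the list alone), neutrophil genes (1.68, 2 of 16 called, 14 higher and 1 lower adjusted over the list alone) and B cell genes (0.72, 1 of 12 called, 5 adjusted over the list alone). So were cell cycle (0.89) and oxidative phosphorylation (0.27), all 5 with an estimated adjusted p of 0.559 or more. Of lists added after the data were examined, 9 of 11 pituitary genes (median -3.78), 4 of 9 salivary gland genes (-2.32) and 0 of 11 serous gland genes (-1.77) were called lower. Single libraries ended 16 of the 18 named calls, all but those of Hyou1 and Car6, and Car6 (highest adjusted p 0.0454) fell under the count filter without any of 6 libraries. Without the OIM library 1, which holds femur transcripts, Ppbp, Prtn3, Retnlg, Pax5 and Ly6g went to 1.02, 1.37, 1.21, 0.94 and 1.75. The call of Pax5 ended without any of 44 libraries, those of Ppbp and Prtn3 without any of 10, Retnlg 5 and Ly6g 3. Smr3a and Bpifa2 went to -2.07 and -2.61 without the WT library 10, and Fshb and Platr9 to -1.57 and -1.81 without the WT library 3. Without the WT library 5 most others lost their calls at close fold changes, such as Krt8 at -1.14 and Dynlrb2 at -0.99, and 11 genes were called.

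**Figure D2:**
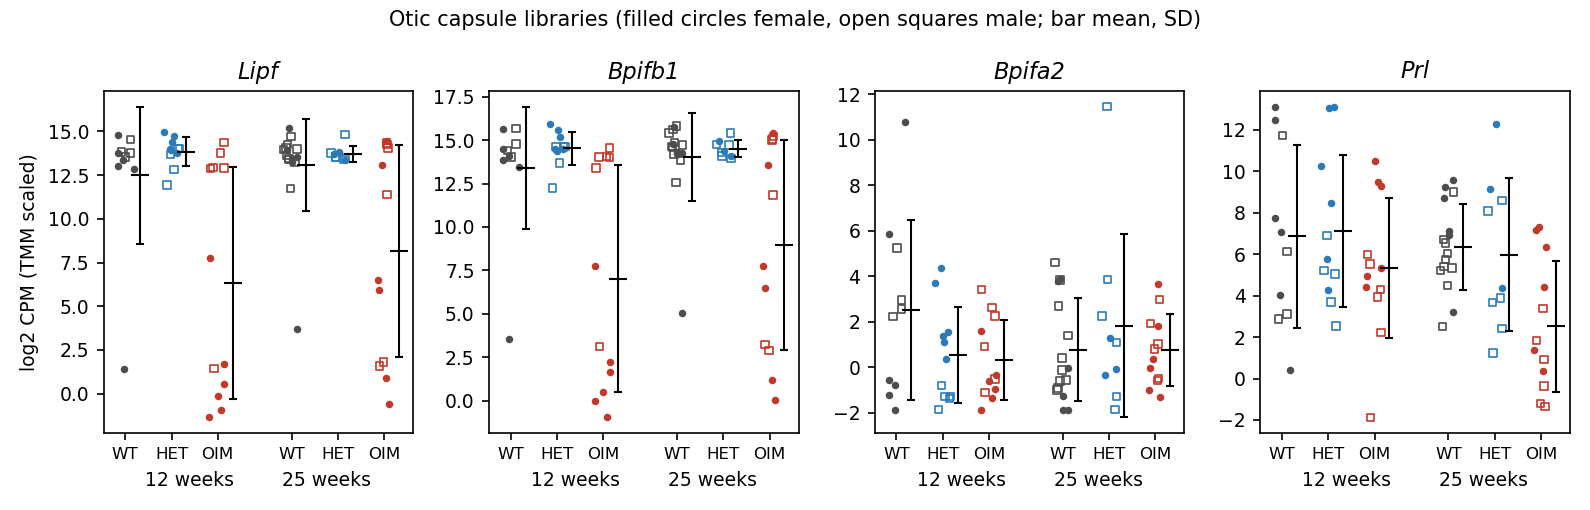
Levels of Lipf, Bpifb1, Bpifa2 and Prl in each otic capsule library, as log2 CPM, by genotype and age; each point is 1 mouse and the bars give the group mean and SD. Lipf and Bpifb1 form a low group of points that holds 7 of 12 OIM libraries and 1 of 10 WT libraries at 12 weeks, under 1000 CPM.

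Lipf and Bpifb1 came in steps between otic capsule libraries. Lipf, a lipase of serous glands, averaged 13300 CPM (SD 8080) in WT, 16700 (SD 7880) in HET and 4840 (SD 6930) in OIM otic capsules at 12 weeks. Bpifb1, a secreted antimicrobial protein of airway glands, averaged 23700 (SD 16700), 28000 (SD 16000) and 7120 (SD 9200). Both genes lay under 1000 CPM, a level chosen after the values were seen, in 7 of 12 OIM, 0 of 11 HET and 1 of 10 WT libraries (OIM against WT, two-sided Fisher's exact p 0.031). At 25 weeks they did so in 6 of 12 OIM, 0 of 9 HET and 1 of 16 WT libraries (Fisher's exact p 0.0228). Both p-values were 0.031 after adjustment over the 4 tests. The OIM library 1 at 12 weeks and 9 at 25 weeks, whose label or content is doubted, are among the low ones. Without the doubted libraries the low ones were 6 of 11 OIM and 1 of 10 WT at 12 weeks (Fisher's exact p 0.0635) and 5 of 11 OIM and 1 of 16 WT at 25 weeks (p 0.0265), with adjusted p of 0.0635 and 0.053. At 12 weeks the low libraries included 6 of 6 OIM females and 1 of 6 OIM males, and at 25 weeks 4 of 6 and 2 of 6. Without the doubted libraries these were 6 of 6 and 0 of 5 at 12 weeks, and 3 of 5 and 2 of 6 at 25 weeks. The low WT library was a female at both ages. Neither gene passed the edgeR test of OIM against WT in otic capsule.

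At 25 weeks the otic capsules of OIM and WT mice differed in 7 genes by edgeR, 6 higher and 1 lower. The clone-named gene CT010467.1 rose by 1.95 (SE 0.35, adjusted p 0.00964, 10 of 12 libraries) and the mitochondrial leucyl-tRNA synthetase gene Lars2 by 1.61 (SE 0.33, adjusted p 0.0352, 9 of 12). CT010467.2 rose by 1.14 (9 of 12), while the chromatin gene Brpf3 fell by 0.50 (SE 0.11, adjusted p 0.0357, 12 of 12). All 4 calls ended without the OIM library 9, at close fold changes (1.80, 1.46, 1.04 and -0.48), and they also ended without other libraries: 2 libraries in all for CT010467.1, 10 each for Lars2 and CT010467.2 and 17 for Brpf3. A further 2292 genes had an unadjusted p under 0.05. The authors' deposited table has 10 genes with the sexes averaged and 75 without sex in the model. The 554 genes lower at 12 weeks had a median of -0.51 and 535 of them kept the sign. Cell cycle genes had a median of -1.31 (15 of 16 lower adjusted over the list alone, camera adjusted p 2.37e-15, estimated adjusted p 0.541). Medians were -1.46 for erythroid genes, -0.66 for airway epithelium, -0.28 for inner ear epithelium, 0.67 for skeletal muscle, 0.35 for oxidative phosphorylation and 0.34 for tendon and fibroblast. Bone matrix genes had 0.32 (camera adjusted p 4.84e-05, estimated adjusted p 0.767). Pituitary and serous gland genes had medians of -3.05 and -0.83 with 0 called.

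The OIM effect in otic capsule differed between the ages for the cell cycle and erythroid lists, and for the B cell list only with the doubted libraries in, and not for single genes. Cell cycle genes had a median interaction of -2.17 (16 of 16 adjusted over the list alone, camera adjusted p 2.35e-34, and an adjusted p of 0.0144 with the estimated correlation). Erythroid genes had -3.41 (13 of 14, estimated adjusted p 0.0144) and B cell genes -1.03 (5 of 12, estimated adjusted p 0.0404). Neutrophil genes had a median of -1.94 (13 of 16) with an estimated adjusted p of 0.097. By fry the adjusted p was 0.0144 for cell cycle and erythroid genes and 0.0471 for B cell genes. The mean level of the erythroid genes, as log2 CPM, went from 3.68 at 12 weeks to 5.27 at 25 weeks in WT, from 4.93 to 4.02 in OIM and from 4.65 to 4.10 in HET, so WT moved most. Without the doubted libraries, of which the OIM 12-week library 1 had the highest erythroid level of its group (7.26), the medians were -3.22 for erythroid, -1.86 for cell cycle and -0.68 for B cell genes (camera adjusted p 5.53e-24, 4.66e-27 and 4.29e-06). With the correlation estimated, erythroid and cell cycle genes still passed without them (adjusted p 0.0328 each) and B cell genes did not (0.154). No single gene passed by edgeR (1106 at an unadjusted p under 0.05), while DESeq2 called 138 and voom 1. There are 159 genes without sex in the model in the authors' deposited table.

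Heterozygous otic capsules at 12 weeks had no gene past the threshold by edgeR (1040 at an unadjusted p under 0.05, 7 by DESeq2, 2 by voom). Their bone lists lay lower than in WT by camera at its preset correlation, and no list passed with the correlation estimated: bone matrix genes had a median of -0.45 (2 of 22 lower adjusted over the list alone, camera adjusted p 4.15e-12, estimated adjusted p 0.172). Matrix proteases had -0.36, chondrocyte genes -0.48 (4 of 15 adjusted over the list alone) and osteocyte genes -0.35 (3 of 17), each with an estimated adjusted p of 0.138. The WT library 7 stood apart from its group with high levels of the disease genes (mean log2 CPM 6.45, others 5.63 to 6.05), and its part in these medians was not tested. Cell cycle genes had a median of 0.94 (8 of 16 higher adjusted over the list alone, estimated adjusted p 0.191), erythroid genes 1.94 (9 of 14) and neutrophil genes 1.21. At 25 weeks 2 genes were called (1090 at an unadjusted p under 0.05). The named one, Car6, rose by 6.37 (SE 1.10, adjusted p 0.00406, 7 of 9 HET libraries), which ended without the HET library 4 (3.64, adjusted p 0.869) or 2 (5.28, adjusted p 0.576), and Car6 fell under the count filter without any of 6 others. Cell cycle genes then had a median of -0.93 (camera adjusted p 1.5e-14, estimated adjusted p 0.243), erythroid genes -1.17, adipocyte genes 0.64 and oxidative phosphorylation 0.27.

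Against HET over both ages, bone matrix genes were called higher and secretory ones lower in the otic capsule of OIM mice, and no list passed camera with the correlation estimated. The mean log2 CPM of the bone matrix list was 5.28 in WT, 4.94 in HET and 5.36 in OIM at 12 weeks, so HET lay below both. At 25 weeks it was 4.46, 4.40 and 4.79. The 12-week OIM library 1, which holds femur transcripts, is included. Bglap, the osteocalcin gene, rose by 0.95 (SE 0.20, adjusted p 0.00852, above the HET median of its age in 22 of 24 OIM libraries) and Bglap2 by 0.80. Ifitm5, an osteoblast membrane protein mutated in a dominant form of the disease, rose by 1.02 (24 of 24), Sp7, the osteoblast transcription factor gene, by 0.65 (22 of 24), Sparc by 0.42 and Col12a1 by 0.93 (SE 0.19, adjusted p 0.0073, 23 of 24). Crosslinking and fibril genes rose with them, Loxl2 by 0.81, Pcolce by 0.40, Adamts2 by 0.42, Thbs2 by 0.74, Fbn1 by 0.62, Fn1 by 0.51, Col14a1 by 0.54 and Col6a1 by 0.53, each in 20 or more of 24 libraries. Dach2, Kcnj13 and Apol7d rose by 1.05, 0.98 and 0.85. Chaperone genes fell, Sdf2l1 by 0.68 (SE 0.14, adjusted p 0.00699, 21 of 24), Manf by 0.39 and Hyou1 by 0.33. Krt18, Krt8 and Tekt1 fell by 1.07, 0.99 and 0.59. The fat genes Ucp1, Cidea and Pparg fell by 1.25 (23 of 24), 0.97 and 0.69, and Platr9 by 3.73. The hormone and salivary genes Fshb, Cga, Car6 and Bpifb2 fell by 4.85 (SE 1.15), 3.72, 3.73 and 3.62.

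This comparison called 986 genes, 176 higher and 810 lower (824 without sex in the model in the authors' deposited table). With the gland scores in the model 0 were called, in males alone 0 and by voom 3777. Bone matrix genes were 13 of 22 called higher, 18 adjusted over the list alone (median 0.50, camera adjusted p 1.27e-14, and an adjusted p of 0.159 with the estimated correlation). Unfolded protein response genes were 12 of 23 lower (17 adjusted over the list alone, camera adjusted p 1.13e-12, estimated adjusted p 0.155). Airway epithelium had 4 of 13 lower (12 adjusted over the list alone), adipocyte genes 4 of 12 lower (9), matrix proteases 7 of 22 higher (13) and tendon 5 of 15 higher (9). Of the added lists, pituitary genes were 8 of 11 lower, salivary gland 5 of 9, serous gland 3 of 11 and brown adipocyte 3 of 7. Leaving out single libraries ended 8 of the 33 named calls: Bpifb2, Car6, Kcnj13, Manf, Pparg, Tekt1, Ucp1 and Wnt16.

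**Figure D3:**
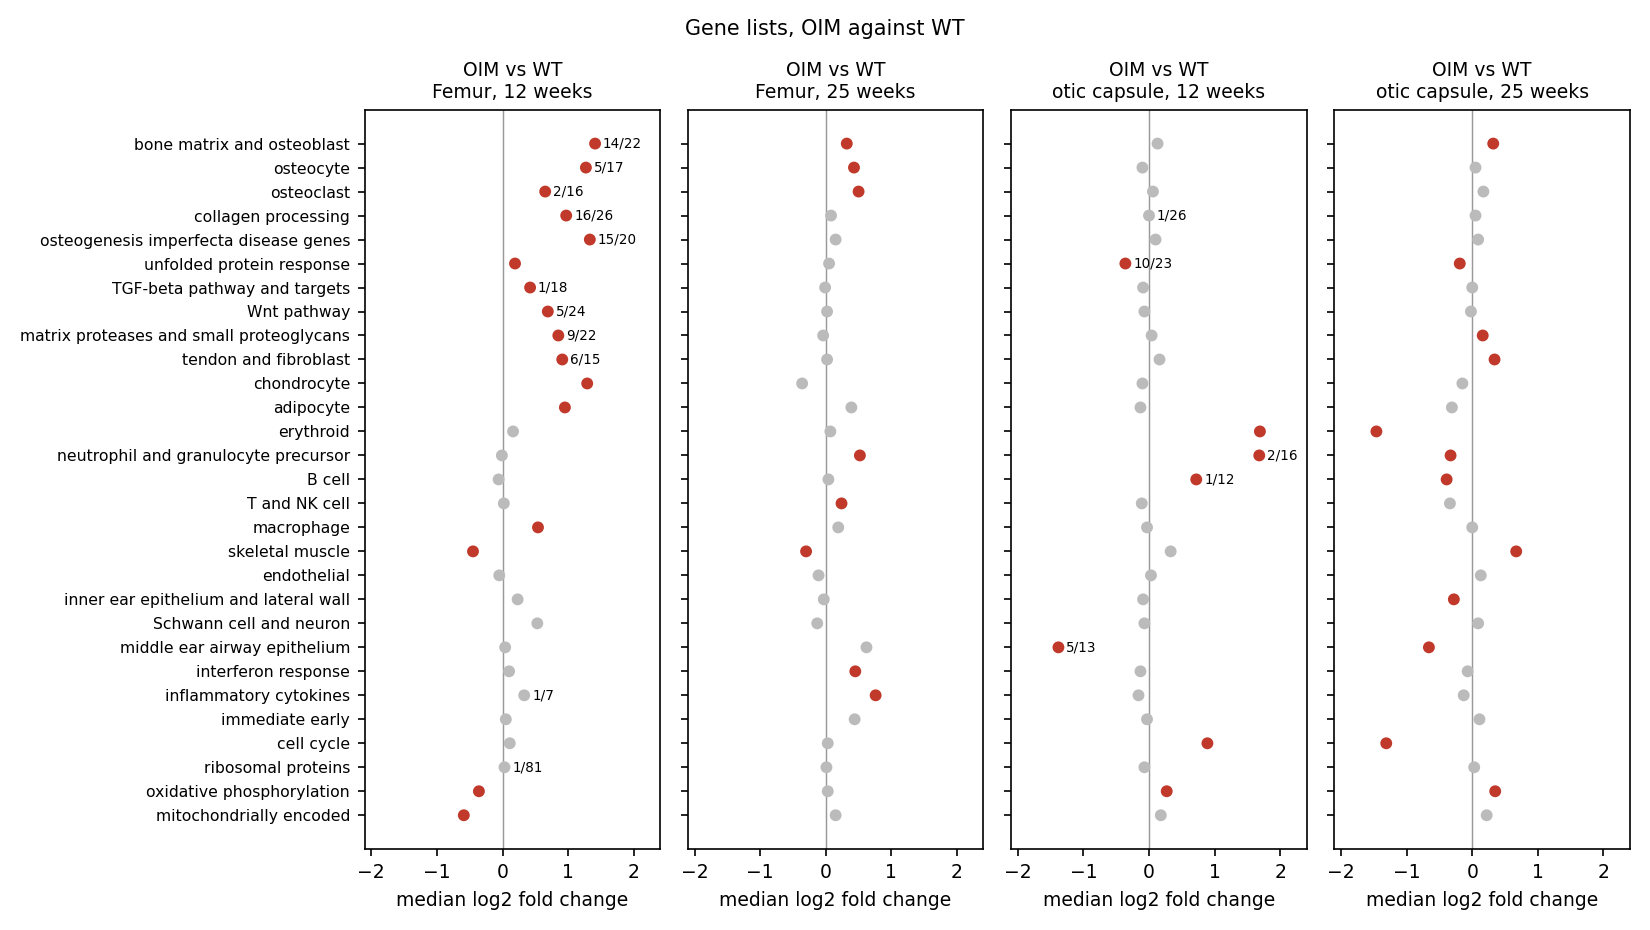
Median log2 fold change of each gene list in OIM against WT, with 1 panel per tissue and age; red points mark a camera adjusted p under 0.05 at the preset correlation, grey points the others, and the numbers beside points give the members called and measured. The bone matrix list has its highest median, 1.41, in femur at 12 weeks.

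The OIM effect differed between the tissues when tested over both ages, with 1316 of 19302 genes called (346 with a more positive and 970 with a more negative effect in otic capsule). Chance is not excluded for such a count. Of 25 groupings of the libraries 2, the real one among them, called as many by a quicker fit (1480, highest other 3457). These groupings swapped the tissues within mice and so mixed tissues that differ in 16593 genes. They therefore cannot decide what chance gives for the interaction. Bone genes raised in femur had lower effects in otic capsule: Panx3 by 2.64 (SE 0.54, adjusted p 0.00119), Irx5 by 1.80, Dkk1 by 1.86 and the osteocyte gene Dmp1 by 1.70. Cthrc1 was lower by 1.47 (SE 0.31), Smpd3 by 1.26, Notum by 1.26, Tcf7 by 1.13 and Ptgs2 by 1.88. In the secretory pathway, Sec24d was lower by 1.12 (SE 0.20, adjusted p 0.000395) and the secretory transcription factor gene Creb3l1 by 1.46. Tent5a was lower by 1.03, Pdia4 by 0.77, Xbp1 by 0.70, Kdelr2 by 0.66 and P4hb by 0.59. The gland genes Lipf, Bpifb1, Dmbt1 and Bpifa1 differed by -5.27 (SE 1.60, adjusted p 0.031), -5.20 (SE 1.49), -4.93 and -3.91. These 4 rest in part on femur libraries that hold head transcripts: Bpifb1 had a log2 fold change of 5.30 in OIM femur at 12 weeks (SE 1.92, adjusted p 0.108). Without the doubted libraries and those mixed with RNA of another tissue Lipf differed by -1.37 (adjusted p 0.505, edgeR), Bpifb1 by -1.94, Dmbt1 by -1.79 and Bpifa1 by -1.09, none called, while Panx3 kept its call at -2.77. More positive in otic capsule were the neuronal genes Pnmal1, Gabra2 and Hpcal4 by 2.63 (SE 0.78, adjusted p 0.0286), 2.63 and 1.86. So were Rlbp1 by 1.82, Odf3l2 by 1.60 and the muscle genes Pvalb and Myl1 by 0.98 and 0.97. Lower in otic capsule were 12 of 23 unfolded protein response genes (15 lower and 1 higher adjusted over the list alone), 11 of 26 of collagen processing (16 and 1), and 8 of 18 osteocyte genes (13). So were 8 of 20 disease genes (13 and 1), 7 of 24 of the Wnt pathway (9) and 4 of 22 of bone matrix (9). Their camera adjusted p ran from 4e-08 to 0.00172, and their estimated adjusted p from 0.406 to 0.418. Libraries on each side are not counted for this difference of differences.

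Few genes were called in both tissues at 12 weeks. The overlap was 6 genes higher in both (2410017I17Rik, Gm10499, H2-Ea, Rps18-ps4, Rps18-ps5 and Rps18-ps6), 2 genes lower in both, Gh and Prl, and 9 higher in femur and lower in otic capsule. Independent lists would share 0.907, 1.05 and 8.77, but both tissues come from the same mice, so these are not the values expected by chance. All 6 of the higher genes are among the 100 whose levels best match between the tissues of a mouse. H2-Ea, a chain of the class II molecule that some mouse haplotypes do not express, had 808 counts over the OIM and 0 over the WT femur libraries at 12 weeks, at least 233.1-fold higher against a floor of 3 counts over the group. In otic capsule it had 546 against 0, at least 144.8-fold higher. It passed 10 counts in 7 of 12 OIM and 0 of 10 WT femur libraries (two-sided Fisher's exact p 0.00535, adjusted 0.0107) and in 8 of 12 and 0 of 10 otic capsule libraries (Fisher's exact p 0.00169, adjusted 0.00676). At 25 weeks the numbers were 8 of 12 and 3 of 15 in femur (Fisher's exact p 0.022, adjusted 0.0293) and 8 of 12 and 5 of 16 in otic capsule (Fisher's exact p 0.125, adjusted 0.125). HET libraries passed 10 counts in 6 of 11 femur and 7 of 11 otic capsule libraries at 12 weeks, and in 5 of 10 and 5 of 9 at 25 weeks. Without the WT library 5 the edgeR call of H2-Ea in otic capsule ended, at a log2 fold change of 8.49 that is fitted over a group without counts.

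**Figure D4:**
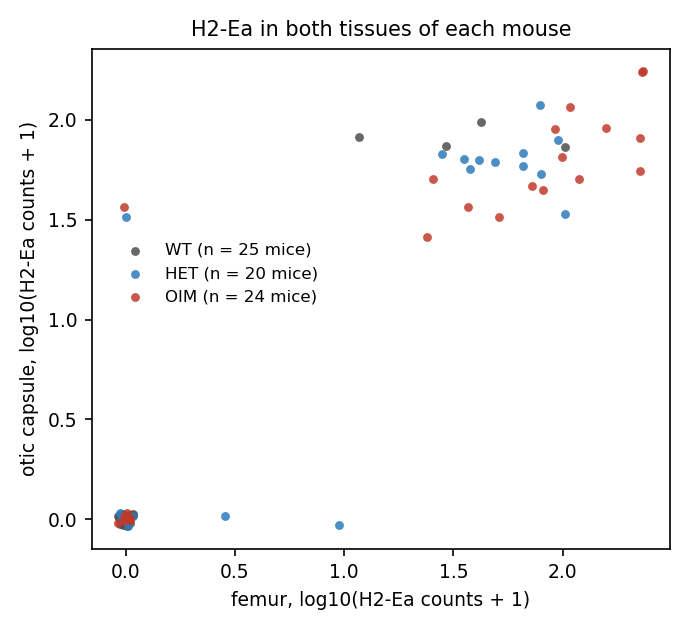
H2-Ea in the femur and the otic capsule of each mouse with both tissues, as log10 of counts plus 1, for 25 WT, 20 HET and 24 OIM mice; each point is 1 mouse, shifted slightly at random. Most mice lie either near 0 in both tissues or high in both.

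The effects of 1 and of 2 oim alleles were compared across genes, which are not independent replicates and share the WT libraries. Over the genes of each tissue, the log2 fold changes of HET and OIM against WT correlated with r 0.538 in femur and 0.505 in otic capsule at 12 weeks. At 25 weeks r was 0.633 and 0.503. Simulated counts without any effect gave 0.523, 0.536, 0.408 and 0.416 from the shared controls alone. With the WT libraries divided between the comparisons the mean values were 0.209, 0.192, 0.224 and 0.346. At 12 weeks r lay within or below the range of the simulations (0.489 to 0.551 in femur, 0.515 to 0.551 in otic capsule), while the covariance, at 0.0735 and 0.068 by the fit used for the draws, exceeded their highest values of 0.0405 and 0.0359. At 25 weeks r exceeded their highest values of 0.438 and 0.431. The simulations drew each gene independently, so they lack the variation between libraries that genes share. Values beyond their range therefore do not show an effect common to HET and OIM. Over the divisions of the WT libraries r ran from -0.125 to 0.427 and from -0.0415 to 0.421 at 12 weeks, and from -0.00356 to 0.351 and from 0.208 to 0.515 at 25 weeks.

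By edgeR no gene had an OIM effect that differed between the sexes. The interaction of genotype and sex had 0 genes by edgeR in femur (400 at an unadjusted p under 0.05, 0 by DESeq2, 0 by voom) and 0 in otic capsule (1447, 19 by DESeq2, 23 by voom). In otic capsule the count by edgeR was 26 without the doubted libraries and 2 without the doubted and mixed ones. Airway epithelium genes had a median of -1.14 in otic capsule (8 of 13 lower adjusted over the list alone, camera adjusted p 1.51e-08, estimated adjusted p 0.696), and oxidative phosphorylation 0.19 in femur (camera adjusted p 3.22e-07, estimated adjusted p 0.864).

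From 12 to 25 weeks, transcripts of bone formation fell in both tissues. In femur Postn, a periosteal matrix gene, fell by 1.17 (SE 0.18, adjusted p 8.22e-05, below the 12-week median of its genotype in 33 of 37 libraries). Cthrc1 fell by 1.22, Bglap2 by 1.15, Col12a1 by 1.19, Loxl2 by 0.99, Col3a1 by 1.02, Thbs2 by 0.97, the collagen chaperone gene Serpinh1 by 0.76 and P3h1 by 0.57, each in 30 or more of 37. The gland and pituitary genes Lipf, Dmbt1, Prl, Bpifb1 and Gh fell by 5.06 (SE 0.88, 24 of 37), 4.8, 4.72, 4.70 and 3.93, and Tubb3 by 1.63. The antibody genes Ighg3 and Igkv4-59 rose by 2.04 (SE 0.36, adjusted p 0.000261, 30 of 37) and 2.05, and Egr1 by 0.95 (22 of 37). In otic capsule Bglap2 and Bglap fell by 1.32 (SE 0.14, adjusted p 5.22e-09, 36 of 37) and 1.25 (SE 0.17, adjusted p 2.16e-06, 35 of 37). Col11a1 fell by 1.24, Prss35 by 1.24 (37 of 37), Ifitm5 by 1.02, Col5a2 by 0.92, Col2a1 by 0.88, Phex by 0.74, Dmp1 by 0.57, Sparc by 0.56 and Pomc by 2.53. The antibody genes Ighg2c, Igkc and Ighm rose by 1.18, 1.17 (SE 0.21, adjusted p 0.000799, 31 of 37) and 0.73, and Ush1g, of the hair bundle, by 0.59.

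The age comparison called 557 genes in femur (135 higher, 422 lower) and 93 in otic capsule (11 higher, 82 lower). In otic capsule chance is not excluded for the count, since 2 of 30 groupings of the libraries, the real one among them, called as many, and the other called 2267. The authors' deposited tables have 960 and 21 without sex in the model. Bone matrix genes were 8 of 22 lower in femur (15 adjusted over the list alone, median -0.58, camera adjusted p 5.75e-23, estimated adjusted p 0.0553). They were 14 of 22 in otic capsule (20 adjusted over the list alone, median -0.49, camera adjusted p 7.17e-58). In otic capsule this also held with an estimated correlation, at an adjusted p of 0.000187. Disease genes (8 of 20, 14 adjusted over the list alone) passed so at an estimated adjusted p of 0.00151. So did osteocyte genes (3 of 17, 0.00248), collagen processing (7 of 26, 0.00563), matrix proteases (4 of 22, 0.00845), tendon (2 of 15, 0.0235) and chondrocyte genes (3 of 15, 0.0235). In femur, collagen processing had 10 of 26 lower (19 lower and 1 higher adjusted over the list alone), matrix proteases 8 of 22, disease genes 6 of 20 and tendon 6 of 15. The tissues, which come from the same mice and so are not independent, shared 46 genes lower with age. Single libraries ended 7 of the 32 named calls in femur (Apol11a, Igkv5-39, Nefm, Snap25, Igkv4-72, Nkd2 and Prl) and 8 of the 28 in otic capsule (mt-Tt, Ctsk, Postn, Ighm, Col11a2, Timp1, Dmp1 and Pomc). Without the HET 12-week femur library 9, Lipf went to -3.13, Dmbt1 to -2.68, Bpifb1 to -2.91, Gh to -3.23 and Prl to -3.51 (adjusted p 0.0792, edgeR). Without the doubted and mixed libraries Lipf, Dmbt1 and Bpifb1 went to 0.34, 0.25 and 0.09, so their fall with age rests on those libraries.

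Female and male libraries differed in 4798 femur genes (2229 higher in females) and 4141 otic capsule genes (1996 higher). Sex coincided with batch but for 3 libraries, so these are differences of sex or batch. Beside Xist (9.95 in femur, 10.18 in otic capsule) and the Y-linked genes, Prl rose by 5.41 in femur (SE 0.90, 26 of 34 females above the male median of their group) and 3.65 in otic capsule. Gbp8 rose by 2.19 and 1.91, and A2m by 2.47 in femur, where Slc15a5 fell by 5.24 (SE 0.29, 34 of 34). Slc30a2 fell by 2.63 in otic capsule (33 of 33). In femur 51 of 77 oxidative phosphorylation genes were lower, as were 8 of 11 immediate early genes, while 12 of 15 B cell, 11 of 15 interferon response and 8 of 12 macrophage genes were higher. In otic capsule 14 of 16 neutrophil and 11 of 16 cell cycle genes were lower, among them Ctsg by 1.33 and Plk1 by 0.92, which changed sign with batch in the model (2.81 and 0.32), as did 17 named genes in all over the alternatives. Of bone matrix genes 9 of 22 were higher, among them Ibsp by 0.67, and the osteocyte gene Dmp1 rose by 0.68 (SE 0.13, 31 of 33). The estimated adjusted p of the listed groups was 0.791 or more, and the sex-linked genes alone passed so (8.93e-20 in femur, 1.28e-23 in otic capsule).

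The tissues differed in 16593 of 19302 genes, 8378 higher in otic capsule and 8215 lower (16833 without sex in the model in the authors' deposited table). Higher were genes of the inner ear, such as Gjb6 by 8.09 (SE 0.32, adjusted p 2.24e-49, in 69 of 69 mice with both tissues), Gjb2 by 7.08 and Slc26a4 by 7.70. Others were Zic2 by 9.25, Kcnk9 by 9.28 and the ciliary regulator gene Foxj1 by 7.12. Lower were the hind limb genes Hoxc10 and Hoxa10 (68 of 69 mice each), whose fitted log2 differences of 14.96 and 11.19 rest on otic capsule libraries without counts (66 and 62 of 70) and are not measured folds. The pooled counts gave log2 ratios of 5.77 and 5.84, or 11.84 and 9.85 without the OIM 12-week otic capsule library 1, which holds limb genes. Lower as well were marrow genes such as Retnlg by 5.76 and Cd5l by 6.14, and the osteoclast integrin gene Itgb3 by 3.49. Type I collagen was lower, Col1a1 by 2.57 (SE 0.27, 66 of 69) and Col1a2 by 2.48. By list, 16 of 17 inner ear, 14 of 14 Schwann cell and neuron and 12 of 13 airway genes were higher. Lower were 80 of 81 ribosomal protein, 75 of 77 oxidative phosphorylation, 15 of 16 neutrophil, 14 of 14 erythroid and 21 of 22 bone matrix genes. The estimated adjusted p of these lists ran from 0.548 to 0.587. Of the added lists 12 of 12 head genes, 11 of 11 serous gland, 9 of 9 salivary gland and 11 of 12 pituitary genes were higher, and 9 of 10 hind limb homeobox genes were lower.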

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

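The tests on mouse labels, on blood cell genes in femur, with gland or muscle scores and without doubted, mixed or single libraries were chosen only after the results they bear on were seen.

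In groups of up to 10 libraries, 1 library stood far apart from the rest of its group in 10 of the values tested over 4 groups (7.04% of them), where chance alone marks about 1 in 20. In the 25-week HET femurs these were library 1 for Schwann cell and neuron genes (mean log2 CPM 2.24, others 0.75 to 1.54), library 6 for interferon response (2.22, others 2.94 to 3.44) and library 2 for immediate early genes (6.46, others 3.98 to 5.23). Among 12-week WT femurs, library 1 stood apart for airway epithelium (4.43, others 0.84 to 2.65) and library 5 for Prl (12.33, others -2.01 to 4.28). In the 25-week HET otic capsules these were library 2 for immediate early genes (6.91, others 4.05 to 5.33) and library 6 for Brpf3 (5.87, others 4.73 to 5.28). Among 12-week WT otic capsules, library 7 stood apart for the osteogenesis imperfecta disease genes (6.45, others 5.63 to 6.05) and for airway epithelium (5.07, others 6.88 to 8.66), and library 10 for Car6 (6.83, others -1.87 to 2.20).

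The OIM effect differed between the tissues in 1316 genes by the interaction test. Chance is not excluded for that count, and the groupings that swapped tissues within mice cannot test it. The largest differences, otic capsule minus femur on the log2 scale, were 2.63 for Pnmal1, 2.63 for Gabra2, 1.86 for Hpcal4, 1.82 for Rlbp1 and 1.60 for Odf3l2, and -5.27 for Lipf, -5.20 for Bpifb1, -4.93 for Dmbt1, -3.91 for Bpifa1 and -2.64 for Panx3. Without the doubted and mixed libraries Lipf went to -1.37, Bpifb1 to -1.94, Dmbt1 to -1.79 and Bpifa1 to -1.09, none called, while Pnmal1 (3.21), Gabra2 (3.6), Hpcal4 (2.17), Rlbp1 (2.18), Odf3l2 (1.53) and Panx3 (-2.77) kept their calls. The OIM effect in otic capsule differed between the ages for erythroid genes (adjusted p 0.0144 by camera with an estimated correlation), cell cycle genes (0.0144) and B cell genes (0.0404), and without the doubted libraries the values were 0.0328, 0.0328 and 0.154.

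Among the 554 genes lower in OIM otic capsules at 12 weeks are gland genes: with pituitary, salivary, serous gland and muscle scores as covariates, 0% of the 541 of them outside those lists were still called, their median log2 fold change went from -1.16 to -0.47 and their median SE from 0.32 to 0.26, so the calls ended because the fold changes shrank. The scores differ with genotype, so they would remove a genotype effect as well. Without the OIM library 1, which holds limb genes, 45.67% were still called, which met the bound written beforehand for 1 library of another tissue as the cause. The median of the 554 genes was -1.08 without it, against -1.18. A bound on that median was added after the share was seen, because leaving out any of 7 other libraries also moved the count. The genes were chosen in a fit that includes the library, so that bound does not exclude it as the cause of the calls. In females alone, all in batch l4, the median was -1.53 (232 called), so differences between sexes or batches do not account for the lower levels there. The 554 genes were chosen in a fit that includes these females, which favours a negative median. Males had -0.75 (1 called), so a part of sex or batch in the size of the effect is not excluded. RNA of neighbouring glands stays a candidate explanation, beside a loss of glands in OIM mice that was not tested.

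The bone matrix and osteocyte genes that lay higher in OIM femur at 12 weeks had a median log2 fold change of 1.38 over 39 measured genes, with 19 called. Libraries of doubted label or content do not account for it, since the median was 1.47 without them. A smaller share of muscle might raise all other cell types alike, but erythroid, neutrophil and B cell genes had a median of 0.04 (quartiles -0.08 to 0.16, against 0.97 to 1.71 for the bone genes). Blood cell genes thus did not rise with the bone genes. The bound first written against this explanation, a median at or under 0, was not met. The bound on quartiles that was met was added after the value was seen. The femurs had been flushed of marrow, and how far that sets blood cell levels was not tested, so the explanation is not excluded. With the muscle score as a covariate the median was 0.81 (58.28% of its size, SE 0.44 to 0.36) and 1 gene was called, and with blood cell and muscle scores 0.59 (42.47%) and 0. The first lies between the bounds set for and against less muscle on the piece, so a change in muscle and a change in bone cells cannot be told apart here.

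The femur library 1 of the 12-week HET group and the femur library 1 of the 12-week OIM group carry the same mouse-specific transcripts: over the 100 genes that best match the tissues of a mouse, r was 0.95 between them, above the 0.85 of the closest other pair of femur libraries with undoubted labels. Against the otic capsule library of the same mouse label r was -0.28 and -0.24, while 65 other mice had r from 0.826 to 0.960, a range that the choice of genes raises. Like background of littermates would not by itself give this mismatch between the tissues of a label. Whether the 2 femurs come from related mice is not settled by these values. The values are consistent with a mislabelled sample in at least 1 of the 2, and the genotype of neither was inferred. Levels were centred on the mean of the tissue, except that the OIM otic capsule library 1 was centred on the femur mean because it holds limb genes, which bears on the -0.24 and on the 0.86 below. Of 69 mice 5 had tissues that did not match each other best, as deviations from group, sex and batch. They were the 4 in doubt for labels and the mouse of the 25-week WT femur library 15. That library is mostly muscle and doubted for content. It is the only male femur of batch l4, so the fit leaves it no deviation and its mismatch tests nothing. Without that fit, r between the tissues of its mouse is among those of the 65 mice. Of the 4 in doubt, r was 0.86 between the otic capsule libraries 1 of the 12-week HET and OIM groups. An undoubted pair with different labels, 25-week OIM 2 and WT 10, had 0.87. Between the femur and otic capsule libraries 1 of the 25-week HET group r was 0.15. Within the mouse of the 25-week WT femur library 2 it was 0.20, and that femur matched the WT femur library 3 at 0.88.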

How the results depend on the processing

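Alternatives that left out doubted or mixed libraries or 1 otic capsule library, or that used muscle or gland scores, were chosen only after the results were seen. Numbers are genes called, with the count as reported in brackets at first mention, and the cause of a change was not tested unless one is given.

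DESeq2 size factors in edgeR and the other count table left all 20 counts within 1.5 times of the reported ones, and so did the mouse as a block for the tissue comparison and its interaction with genotype. The tissue comparison and the interaction with sex in femur stayed within that bound under each alternative run. So did the sex comparison in femur (4798), but its fits with batch and in the WT libraries of batch l4 at 25 weeks rest on 1 male library that is mostly muscle and do not support the count. The sex comparison in otic capsule (4141) gave 6967 by voom, 1523 for the WT libraries of batch l4 at 25 weeks alone and 6631 without doubted and mixed libraries. The interaction with tissue (1316) gave 4593 by voom, 2537 without batch and 518 in females.

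For OIM against WT in femur at 12 weeks (544), voom called 2756, the fit without sex and batch 337, females alone 0 and males alone 0, composition scores 2 and the muscle score 27. Leaving out 1 library gave 2.7e+02 (OIM 6) to 997 (OIM 5), and WT 2 and WT 3 also moved the count. At 25 weeks (0), DESeq2 called 5, voom 495, the fits without batch 1 and without sex and batch 2, the muscle score 4, and leaving out WT 8 gave 2. In otic capsule at 12 weeks (585), DESeq2 called 916, no filter 365, females 372, males 1 (median log2 fold change of the 554 lower genes -1.53 and -0.75, SE 0.44 and 0.42), omission of doubted libraries 284, gland scores 0, and omission of the OIM library 1 2.7e+02. Leaving out 1 library gave 11 (WT 5) to 787 (25-week OIM 9), and WT 2 and OIM 1, 7, 8, 9, 10 and 11 also moved the count. At 25 weeks (7), DESeq2 called 16, voom 408, no filter 4, females 0, males 0, omission of doubted and mixed libraries 0 and gland scores 0. Leaving out 1 library there gave 0 (OIM 2 and OIM 9), 1 (OIM 12 and WT 1, 2, 3, 7, 8, 9 and 14), 11 (OIM 6) and 20 (OIM 1).

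For HET against WT in femur at 12 weeks (4), DESeq2 called 11, voom 1, females 25 and males 0, and leaving out WT 5 or HET 7 gave 2 (highest 5). At 25 weeks (0), voom called 4, males 1, composition scores 2 and omission of doubted and mixed libraries 1. In otic capsule at 12 weeks (0), DESeq2 called 7, voom 2 and leaving out the 25-week HET 4 gave 3. At 25 weeks (2), DESeq2 called 0, voom 344, no filter 5, the fits without batch and without sex and batch 4 each, females 0, males 1, composition scores 0 and gland scores 0, and leaving out any of 50 libraries gave 0 to 1 (highest of all 3).

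For OIM against HET in femur (107), DESeq2 called 409, voom 2145, no filter 53, the fits without batch 37 and without sex and batch 27, females 390 and males 0. Composition scores gave 62, the muscle score 698, omission of doubted libraries 514 and of doubted and mixed ones 351, and single omissions of 38 libraries gave 48 (25-week OIM 10) to 611 (25-week OIM 7). In otic capsule (986), voom called 3777, males 0, composition scores 1563, gland scores 0 and omission of doubted and mixed libraries 1976. Leaving out the 25-week HET 8 or 9 gave 530 and 609, and the highest was 1384 (25-week OIM 1).

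For age in femur (557), voom called 1198, females 82, males 94, composition scores 939, the muscle score 1021 and omission of doubted and mixed libraries 341. In otic capsule (93), DESeq2 called 144, voom 216, females 12, males 8, gland scores 140, omission of doubted and mixed libraries 174, and leaving out the 25-week OIM 9 gave 166 (lowest 70, 12-week OIM 6). For the interaction with age in femur (0), voom called 13, and leaving out the 12-week WT 1 or the 25-week OIM 8 gave 1 and 2. In otic capsule (0), DESeq2 called 138, voom 1 and no filter 1. Leaving out the 12-week WT 4 or 6, the 12-week OIM 5 or the 25-week HET 4 gave 1 there, and the 25-week OIM 1 gave 160. For the interaction with sex in otic capsule (0), DESeq2 called 19, voom 23, omission of doubted libraries 26 and of doubted and mixed ones 2.

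The replicate numbers of the titles do not pair libraries. The median correlation of same-numbered libraries of a tissue, as deviations from their group means, was 0.0493 in femur (159 pairs) and 0.00869 in otic capsule (154 pairs), and 68 and 54 pairs had r over 0.1. With that number as a block the counts were 1 for HET against WT in femur at 12 weeks, 1 and 0 for OIM against WT in otic capsule at 12 and 25 weeks, 0 for HET against WT in otic capsule at 25 weeks, 334 for OIM against HET in otic capsule, and 179 and 32 for age in femur and otic capsule. The 585 genes of OIM otic capsule at 12 weeks kept their sign, with a median absolute log2 fold change of 1.02 against 1.19 and a median SE of 0.37 against 0.33. The 986 genes of OIM against HET in otic capsule kept theirs, with 0.67 against 0.70 and an SE of 0.20 against 0.19.

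Of 600 list tests, camera at its preset correlation called 248, camera with estimated correlations 12 and fry 90. The correlation of HET and OIM effects fell to 0.209 and 0.224 in femur at 12 and 25 weeks, and to 0.192 and 0.346 in otic capsule, when the WT libraries were divided between both.

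Named genes held their result in 9061 combinations of a gene not called and an alternative and in 3408 of a called gene and an alternative. In 763 a call was lost, in 268 one was gained and in 54 a called gene changed sign. The 9061 include 238 where a gene that passed neither way changed sign. Of the named calls of OIM against WT at 12 weeks, 0 of 31 in femur and 0 of 18 in otic capsule held under every alternative, and 0 did in any comparison of genotypes within a tissue. The 54 were, in OIM otic capsule at 12 weeks with gland scores, Smr3a 0.45, Fshb 0.82 and Platr9 0.54, and for HET in otic capsule at 25 weeks in females, Car6 -0.72. For age in femur without doubted and mixed libraries they were Lipf 0.34, Dmbt1 0.25, Bpifb1 0.09 and Snap25 0.10. The rest concern sex. With a batch term, sex and batch are separated by the males of batch l4 alone, 1 femur library (25-week WT 15, which is mostly muscle) and 2 otic capsule libraries, so the femur values are not read as changes of the sex result. They were Cd3d 6.46, Tie1 0.33, Esam 0.25, Junb 1.94, Dusp1 0.34, Ier2 0.53, Rpl6 -0.30, Rps4x -0.61 and Rps6 -0.10. In otic capsule they were Bc1 -1.25, Pdpn -0.37, Rspo3 -0.27, Wnt5a -0.60, Ogn -0.30, Ctsg 2.81, Fcnb 2.11, Tectb -0.48, Dct -0.79, Kcne1 -0.86, Btg2 0.36, Ier2 0.15, Nr4a1 0.37, Plk1 0.32, Aurka 0.13 and Tpx2 0.24. In the WT libraries of batch l4 at 25 weeks alone, where that library is the only male femur, the values were Tie1 0.45, Esam 0.39, Junb 2.08, Dusp1 0.47, Ier2 0.87, Rpl6 -0.14, Rps4x -0.45 and Uqcrc1 0.03. The otic capsule values were Bc1 -1.55, Pdpn -0.26, Rspo3 -0.38, Wnt5a -0.62, Ogn -0.26, Lcn2 0.13, Dct -1.05, Kcne1 -1.03, Btg2 0.31, Ier2 0.15, Nr4a1 0.11, Plk1 0.16 and Tpx2 0.10.

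Other groupings of the libraries, 30 each with the real one and drawn within age and sex or the like, were tested for every count. For OIM against WT at 12 weeks in femur (544, highest other 76) and otic capsule (585, highest other 354) and at 25 weeks in otic capsule (7, highest other 2), 1 of 30 groupings, the real one, gave as many. That is the smallest share that 30 groupings can give, and it was not adjusted over the 20 comparisons. Chance is thereby made less likely for each count and is not excluded. The same held for OIM against HET in femur (107, highest other 0) and otic capsule (986, highest other 2), for age in femur (557, highest other 7) and for sex in femur (4798, highest other 4) and otic capsule (4141, highest other 0). More groupings than the real one gave as many for HET against WT in femur at 12 weeks (4, highest other 5, with 5 of 30 as large) and in otic capsule at 25 weeks (2, highest other 2, with 2 of 30). So they did for age in otic capsule (93, highest other 2267, with 2 of 30). A count of 0 is reached by each of the 30 groupings: the highest others were 2 for OIM femur at 25 weeks, 2748 for HET femur at 25 weeks, 1109 for HET otic capsule at 12 weeks, 1 and 0 for the interactions with age in femur and otic capsule, and 3 and 2 for those with sex. For the tissues, swapped within mice in 25 groupings by a quicker fit, only the real grouping gave as many for the comparison (16662, highest other 3928). For the interaction 2 of 25 did (1480, highest other 3457), but these swaps mix the 2 tissues within each group. They therefore cannot decide what chance gives for the interaction. Groupings that called 2748 and 1109 genes where the real count was 0, and 2267 where it was 93, point to a structure of the samples, whose source was not tested.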

Other observations

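The tests on agreement of H2-Ea between tissues and on clock genes were chosen only after their results were seen. Genes of the circadian clock and of glucocorticoid response were among those that separated groups in femur. In OIM against HET femurs 4 of 16 were called lower (median log2 fold change -0.42), and in females against males 7 of 16 in femur (median -0.44) and 3 of 16 in otic capsule (median -0.26), with 0 of 16 called in OIM against WT at either age in either tissue. In HET against WT 0 of 16 were called, but 15 of 16 lay above 0 at 12 weeks in both tissues (medians 0.44 in femur and 0.38 in otic capsule), and at 25 weeks the medians were -0.05 and 0.13. In OIM against WT femurs the medians were -0.22 at 12 weeks and -0.14 at 25 weeks. Of the brown fat genes 3 of 7 were called lower in OIM than in HET otic capsules while 3 of 7 lay above 0 (median -0.20), with -1.25 for Ucp1 and -0.97 for Cidea, while 0 of 7 were called in OIM against WT. Without the 25-week HET library 8 the adjusted p of Ucp1 was 0.0562 (edgeR).

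The clock genes may follow the hour or the handling at dissection, which the tissues of a mouse share. Of the 16 genes 9 are among the 100 that best match the tissues of a mouse, so a correlation over all 16 (r 0.832) tests nothing. The mean level of the other 7, as deviations from group, sex and batch, correlated between the femur and the otic capsule of 69 mice (r 0.5348, rho 0.562, permutation p 1e-05 for each, the smallest that the permutations can give). The hour of dissection was not used here, and a stress response of the animals would give the same correlation.

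Head transcripts in femur libraries mark mixed samples, and limb transcripts in an otic capsule library put its label in doubt. The 12-week WT femur library 1, the OIM femur libraries 3 and 4 and the HET femur library 9 held transcripts of the head. The 12-week WT femur library 5 held pituitary transcripts (Prl at log2 CPM 12.33, Gh at 9.80) at low levels of Zic2, Lipf and Bpifb1, was not counted as mixed and stayed in the fits without mixed libraries. Serous gland genes had a median log2 fold change of 4.61 in OIM against WT femur at 12 weeks with 0 of 4 called, and 4 of 4 fell with age in femur, where 0 of the 25-week libraries were so marked, although the 25-week HET femur library 1, whose label is doubted, had Lipf at log2 CPM 6.75 and Bpifb1 at 7.58. The 25-week OIM otic capsule library 9 lacked inner ear transcripts, the 12-week OIM otic capsule library 1 held hind limb homeobox genes, and the 25-week WT femur library 15 was mostly muscle. All stayed in under their labels.

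H2-Ea passed 10 counts in both or neither tissue in 66 of 69 mice (95.65%), against 50.58% for independent tissues. It is likely on or off in a whole mouse. The mice of the doubted 12-week femur pair are 2 of the 3 exceptions, with 0 counts in femur and 31 and 38 in otic capsule. An H2 haplotype that segregates in the stock is a candidate explanation. 2410017I17Rik and Gm10499, higher in both tissues and matching within mice, lie within 5 Mb. Genes there were called at an odds ratio of 1.188 in femur (interval 0.533 to 2.31, Fisher's exact p 0.576). In otic capsule it was 1.628 (0.824 to 2.92, p 0.132). A haplotype need not alter most of these 232 and 238 genes, so it stays open.

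A chromosome segment passed on with the oim allele was tested around Col1a2. Within 20 Mb 3 of 70 femur genes and 3 of 80 otic capsule genes were called in OIM against WT at 12 weeks, odds ratios of 1.314 (Fisher's exact p 0.503) and 1.184 (p 0.743). The intervals, 0.264 to 4.03 and 0.238 to 3.61, leave a linked effect neither shown nor excluded, and few genes lie in the span.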
